A study of Mus musculus with 8 samples.

How the data were processed

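Gene expression was measured in mouse embryonic stem cells and day-2 embryoid bodies on 8 Illumina bead arrays, hybridised with biotin-labelled cRNA prepared from total RNA per the labels' protocols. The groups were taken from the sample titles. They were undifferentiated E14 stem cells (ESC, 2 arrays), embryoid bodies after 2 days (EB2, 2 arrays) and embryoid bodies formed for 2 days with streptozotocin (2 arrays). The others were ZHBTc4 stem cells with doxycycline (1 array) and ZHBTc4 stem cells with doxycycline and streptozotocin (1 array). The labels give no dose and no duration for either drug, and they do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

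The deposited table used for every main result holds 25697 probes, with the mean bead intensity of each probe on each array on a linear scale and without background subtraction, as the lowest intensity of every array lay above 100. The same deposited table gives a detection p-value per probe and array, named as such per the file headers, and its values come in steps of 1/798. A second deposited table holds log2 values for 12222 of these probes. Its values differed by at most 0.005 from quantile-normalised log2 intensities of the same probes, each of its columns had a median of 9.55, and each correlated best with its own array. Its log2 scale was inferred from this match, and the rule by which its probes were kept is not given in the sources used here. It held all 12047 probes with a detection p-value under 0.05 on at least 4 of the 8 arrays, and 175 others. The scanner software, the array type and the genome build of the probe coordinates are not given in the sources used here. Probes were named through a table of mouse genes (assembly GRCm38.p6, used for names alone): 23788 through the gene ID in the deposited table and 1148 through an accession, while 761 kept the symbol in the deposited table. The named probes covered 17940 genes.

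Intensities of all 8 arrays were background-corrected and normalised together with limma 3.58.1 in R 4.3.3 (neqc: normexp with negative controls inferred from the detection p-values, offset 16, quantile normalisation, log2). A probe was kept when its detection p-value was under 0.01 on at least 2 of the 6 E14 arrays, which left 11011 probes. Each gene was represented by its kept probe with the highest mean log2 intensity over the 6 E14 arrays, giving 8324 genes. Probes of a gene disagreed in sign, both past the test, in 0 of 710, 0 of 326 and 1 of 427 changed genes with several probes, for EB2 against ESC, streptozotocin-treated EB2 against EB2 and streptozotocin-treated EB2 against ESC, and the exception was Irgm1. A group-means model of the 6 E14 arrays was fitted with lmFit and eBayes (trend on intensity), with 3 residual degrees of freedom and 7.2 from the prior. The p-values of each of the 3 contrasts were adjusted over all genes tested with Benjamini and Hochberg's method, and 0.05 was the threshold. Errors given with log2 changes are standard errors of that fit, and errors given with log2 intensities are SDs over 2 arrays. The number of arrays limits the precision: the median standard error of a log2 change was 0.15.

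A gene whose chosen probe was not detected (detection p-value of 0.01 or more) on any array of a group has only a bound there. The change is then given as "at least N-fold": the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the lowest detected signal and the probe's own signal. No fold is given where this ratio is under 1 or neither group was detected.

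Before the data were examined, 20 gene lists with 376 genes, the tests, the processing alternatives and the rule for naming genes were fixed. For each E14 contrast the rule takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, and for the ZHBTc4 pair the 8 largest differences in each direction among genes detected on both arrays. It adds Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, Fgf5, T, Gata6, Cdx2, Ogt and Oga, and up to 4 members of each list with the largest changes. Predicted genes, clone names and accessions were skipped in the naming. Results of a few single genes are not reported here, among them 1 of the genes that went the other way in ZHBTc4, although all counts and list tests include them. Where 5 or fewer members of a list changed in a direction, members are named, and these and any other genes outside the rule were chosen after their values were seen.

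Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast, again with a correlation estimated from the data, and with limma's fry. With an estimated correlation camera tests on the 3 residual degrees of freedom of the fit. Its p-values then rise even where genes are not correlated. The list of known Oct4 targets marked in the deposited table, a list of interferon and MHC class I genes, and a list of amino acid synthesis and ATF4 response genes were added after the data were seen, as were the correlation with separate EB2 arrays and that of the embryoid body changes with the ZHBTc4 differences. Counts within a list are given over all genes tested and adjusted over the list alone. The ZHBTc4 pair has 1 array per condition and was given no test. It was described over 8549 genes detected on at least 1 of the 2 arrays, and each list's median was placed among the medians of 10000 random lists of the same size matched on mean intensity.

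Correlations of changes are Pearson correlations across genes, which are not independent replicates. The EB2 arrays enter 2 of the contrasts with opposite signs, so 100 sets of unchanged groups sharing those arrays were simulated to give the correlation, covariance and overlap that arise with no effect, and the correlation was computed again with a different EB2 array in each contrast. The simulation was repeated with deviations shared by arrays of the same replicate number.

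The procedure was tested on simulated data for 8324 genes, of which 67, 67 and 66 had been given 1.5-fold, 2-fold and 4-fold changes per contrast. For the contrasts of EB2 against ESC, treated EB2 against EB2 and treated EB2 against ESC, it recovered 53.7%, 67.2% and 58.2% of genes changed 1.5-fold, 92.5%, 89.6% and 91.0% of those changed 2-fold, and 100% of those changed 4-fold. It made 17, 10 and 15 false calls. A planted list was called in each contrast and 0 of the 19 other lists were. The simulated genes varied independently and these lists were random. The test therefore does not show how often lists of correlated genes are called falsely, and estimated correlations in the data reached 0.543 (LIF and Stat3 list).

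The alternatives tried were no background correction, an offset of 50, cyclic loess or median scaling in place of quantile normalisation, no filter, detection on all 6 E14 arrays (for ZHBTc4, on both of its arrays), the deposited log2 values, the 6 E14 arrays normalised alone, all 8 arrays in the fit, no trend in the prior, the mean of all probes of a gene, the replicate number as a block, a minimum change of 2-fold, the other list tests, and each E14 array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.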

Results

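The series holds 8 arrays of mouse cells. E14 embryonic stem cells were profiled undifferentiated (ESC), as embryoid bodies grown for 2 days (EB2) and as embryoid bodies grown for 2 days with streptozotocin, with 2 arrays each. Embryoid bodies are aggregates in which stem cells begin to differentiate. Streptozotocin is a glucosamine-nitrosourea that alkylates DNA and is commonly described as an inhibitor of the enzyme O-GlcNAcase, which was not measured here. The series title calls it an inhibitor of O-GlcNAcylation. O-GlcNAcylation is the attachment of N-acetylglucosamine to intracellular proteins. ZHBTc4, a stem cell line in which doxycycline switches off the only working copy of Pou5f1 (Oct4, the core pluripotency factor), was profiled with doxycycline and with doxycycline plus streptozotocin, with 1 array each. Between 10205 and 11011 of the 25697 probes were detected per array (39.7% to 42.8%), and median intensities ran from 231.7 to 252.5.

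Pou5f1 matched the titles and cell types of the 8 arrays, while the source name of the ZHBTc4 samples reads E14 stem cell, which its level goes against. Its normalised log2 intensity was 14.16 ± 0.14 (SD, n = 6) over the E14 arrays and 5.45 and 5.44 on the ZHBTc4 arrays, where it was not detected, a level at least 176-fold lower. The probe lies on chromosome 17 from 35646952 to 35647001 in the coordinates of the deposited table, whose genome build is not given in the sources used here. Cdx2 and Gata3, transcription factors of the trophectoderm, were detected in ZHBTc4 alone, with log2 intensities of 8.39 and 8.81 for Cdx2 and of 9.48 and 10.17 for Gata3 without and with streptozotocin. Replicate arrays correlated across genes at 0.991 to 0.993. The principal component with 53.1% of the variance separated ZHBTc4 from E14, and the next, with 29.9%, ordered the E14 arrays as ESC (39.1 and 39.0), EB2 with streptozotocin (-0.7 and -6.3) and EB2 (-27.8 and -32.1).

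**Figure D1:**
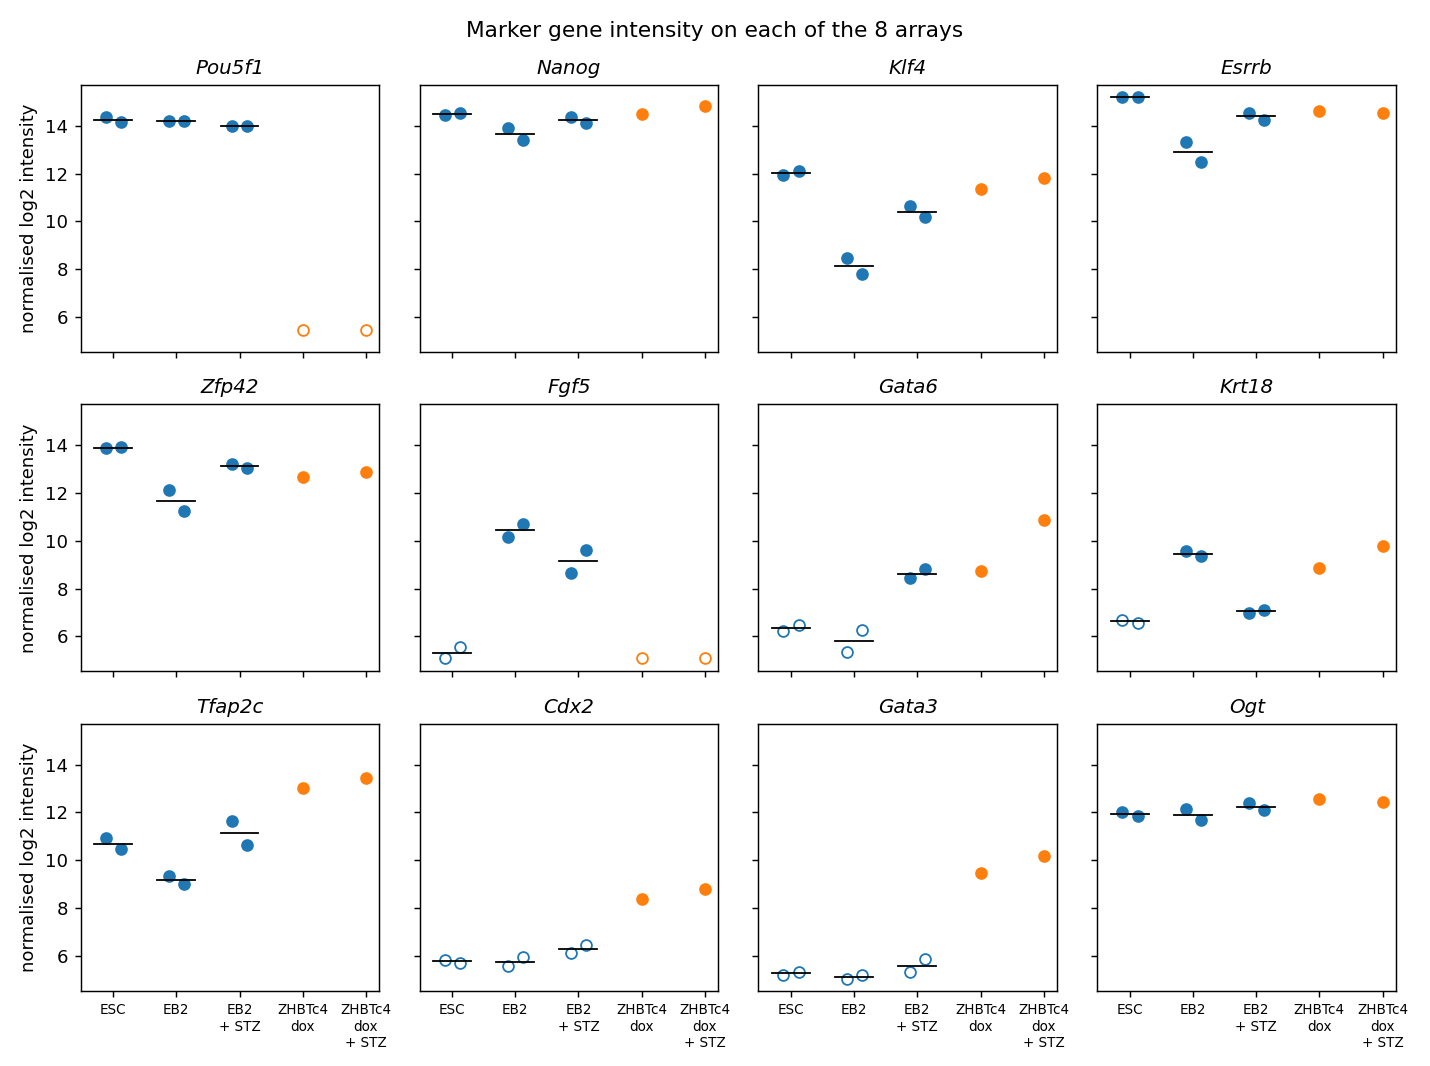
Normalised log2 intensity (vertical axis) of 12 marker genes on each of the 8 arrays (points; blue E14, orange ZHBTc4; open points were not detected; lines are means of 2 arrays). Klf4, Esrrb and Zfp42 lay lower in EB2 than in ESC and in between with streptozotocin, while Pou5f1 was not detected in ZHBTc4 at 5.45 and 5.44.

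The changes of embryoid body formation were measured by comparing EB2 with ESC. Over 2 days transcripts of the naive, ground-state pluripotency network fell and those of the primed, post-implantation epiblast rose, list shifts that limma camera called at the preset correlation but not with an estimated one (adjusted p = 0.42 for both). Klf4, a naive transcription factor that responds to the cytokine LIF, fell from 12.02 ± 0.11 to 8.14 ± 0.48 on the log2 scale (SD, n = 2), or 14.8-fold. Fgf5, the classical marker of the primed epiblast, was not detected in ESC and was at least 10.9-fold higher in EB2 (limma adjusted p = 1.11e-06). Pou5f1 and Sox2 differed by -0.06 ± 0.08 and -0.40 ± 0.15 (SE), with limma adjusted p = 0.604 and 0.0569 (0.5 and 0.014 with the replicate number as a block). In all, 2968 of 8324 genes changed (limma adjusted p under 0.05), of which 1623 rose and 1345 fell; with median scaling in place of quantile normalisation 1220 rose and 2270 fell. At least 2-fold were 837, with groups not detected held at their bounds. In every changed gene the arrays of the groups did not overlap, which held for 67.6% of all genes against 33.3% by chance.

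Of 13 naive pluripotency genes tested, 12 fell and 0 rose, both over all genes and adjusted over the list alone, with a median log2 change of -2.30 (limma camera adjusted p = 7.8e-07; adjusted p = 0.42 with an estimated correlation). Beside Klf4, the list's largest falls were in Tbx3 (-3.66 ± 0.17), Tcl1, a cofactor of Akt (-2.90 ± 0.41), and Klf5 (-2.61 ± 0.17). Esrrb fell by 2.30 and Zfp42 (Rex1) fell by 2.22, whereas Nanog fell by 0.84 ± 0.14 (limma adjusted p = 0.00108). Of 13 primed epiblast genes, 12 rose and 0 fell (13 rose adjusted over the list alone), with a median of 2.30 (camera adjusted p = 4.9e-09; adjusted p = 0.42 with an estimated correlation). Sall2 rose by 4.06 ± 0.21 and the epiblast transcription factor Otx2 by 3.21 ± 0.13. Of 15 general pluripotency genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone), with a median of -0.09. Camera did not call this list (adjusted p = 0.19), while limma's fry did (adjusted p = 0.006). Tdh, the threonine dehydrogenase of mouse stem cells, was at -2.18 ± 0.15 and Dnmt3l, a cofactor of de novo DNA methylation, at -1.26 ± 0.07. L1td1 and Sall4 were also among those that fell, and the gene that rose was Zfp281, a call lost without ESC replicate 1 (adjusted p = 0.2).

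Targets of LIF and its transducer Stat3 fell together: 9 of 11 fell and 0 rose (10 fell adjusted over the list alone), with a median of -2.07 (camera adjusted p = 5.8e-07; adjusted p = 0.42 with an estimated correlation). Socs3, the feedback inhibitor of the pathway, fell 58.7-fold. Gbx2 fell by 3.23 ± 0.13, and Bcl3 was at least 7.61-fold lower and no longer detected (limma adjusted p = 1.31e-05). Of 10 genes that respond to FGF and ERK signalling, 8 fell and 1 rose over all genes and over the list alone (median -0.89, camera adjusted p = 0.0012; adjusted p = 0.42 with an estimated correlation), including Egr1 (-2.54 ± 0.37), Etv4 (-2.42 ± 0.13) and Spry4 (-1.95 ± 0.15). The gene that rose was Dusp4, a call lost without ESC replicate 1 (adjusted p = 0.21). Of 20 p53 targets, 9 rose and 0 fell by either count, with a median of 0.35 (camera adjusted p = 0.02; adjusted p = 0.42 with an estimated correlation), led by Gadd45g (3.52 ± 0.36) and the pro-apoptotic Bbc3 (1.06 ± 0.10). Its median was 0.17 with median scaling, and the list call was lost without ESC replicate 2 (camera adjusted p = 0.05) or EB2 replicate 1 (camera adjusted p = 0.051).

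Other large rises were in Enpp2 (autotaxin, at least 25.5-fold), the carbonic anhydrase Car4 (at least 15.3-fold), Vrtn (at least 8.77-fold), Kif21a (at least 8.22-fold), Zfp608 (at least 7.78-fold), Grm6 (at least 6.87-fold) and the iron exporter Slc40a1 (19.3-fold), with limma adjusted p from 9.44e-08 to 1.37e-06. Other large falls were in Mras (at least 27.8-fold, not detected in EB2), the helix-loop-helix factor Msc (37.0-fold), Emp1 (36.5-fold), Spink1 (35.7-fold), Myl4 (21.2-fold), Pcolce (18.9-fold), the laminin chain Lama1 (17.1-fold), Bmp4 (15.6-fold) and Kdelr3 (at least 7.62-fold), with limma adjusted p from 9.44e-08 to 4.49e-06.

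Lineage lists went both ways, and camera found no shift (adjusted p from 0.34 to 0.95). Of 10 mesendoderm genes 2 rose and 5 fell (median -0.60, or -0.26 with members not detected in a group at their bounds). Lefty1 rose by 2.00 ± 0.13, Fgf8 was at least 2.37-fold higher (limma adjusted p = 2.51e-05) and Chrd at least 2.82-fold lower (limma adjusted p = 0.000152), and Sp5, Evx1, Hhex and Lefty2 fell too. Of 15 primitive and visceral endoderm genes 3 rose and 6 fell (4 and 7 adjusted over the list alone; median -0.54, or 0.00 with bounds), the rises being in Dab2, Serpinh1 and Amn. Of 9 trophectoderm genes 2 rose, Krt18 and Cdh3, and 3 fell, Tfap2c, Peg10 and Tead4 (median -0.08). Of 8 later mesoderm genes 3 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of 0.01, or 0.19 with bounds, and a mean of -0.30. Msx1, Isl1 and Lmo2 rose, and Bmp4 and Meis1 fell. The calls of Lefty2, Amn and Evx1 were lost without ESC replicate 1 (adjusted p = 0.26, 0.13 and 0.061). Krt18, a keratin of simple epithelia, was at least 5.54-fold higher in EB2 (limma adjusted p = 2.09e-06), and Tfap2c, a trophectoderm and germline factor, fell by 1.53 ± 0.28. The primitive streak factor T was not detected on any of the 8 arrays.

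Camera also found no shift in the remaining tested lists, with adjusted p from 0.34 to 0.95. In the O-GlcNAc and hexosamine list 2 of 11 rose and 4 fell (2 and 5 adjusted over the list alone; median -0.25), with Renbp down by 0.99 ± 0.15 and Gfpt2, which makes glucosamine 6-phosphate, down by 0.67 ± 0.14. Pgm3 and Gnpda1 fell too, and Gnpda2 and Gne rose. Ogt, the O-GlcNAc transferase, differed by -0.03 ± 0.16 (limma adjusted p = 0.894), and Oga, the O-GlcNAcase, was not detected on any array. Oga has only 1 probe here, so an absent transcript cannot be told from a probe that does not read it. Among 16 genes of alkylation and base excision repair Lig3 and Mutyh rose and Apex1 fell (median 0.05), and among 15 genes of the unfolded protein and integrated stress response Chac1, Herpud1 and Psat1 rose and 0 fell (median 0.09). Among 20 genes of glycolysis and hypoxia 5 rose (Ddit4, Egln3, Vegfa, Aldoa and Pfkl) and 6 fell, and the median was 0.07 although camera's direction was down. Cholesterol synthesis had 3 of 15 up and 0 down (median 0.16), with Fdps and Sqle among those up. The mitotic list had 1 of 13 up, Top2a (median 0.07), and the heat shock list 1 of 8 up, Bag3, and 1 down (median -0.13), with Hspb1 down by 2.30 ± 0.10. Limma's fry did call the heat shock list (adjusted p = 0.006, mean -0.3). Of these calls, those of Apex1, Pgm3, Vegfa, Aldoa, Pfkl, Bag3 and Mutyh were lost without ESC replicate 1 (adjusted p = 0.11, 0.15, 0.15, 0.13, 0.14, 0.069 and 0.079). Those of Gne, Fdps, Sqle and Top2a were lost without ESC replicate 2 (adjusted p = 0.19, 0.12, 0.13 and 0.057), and that of Gnpda2 without EB2 replicate 1 (adjusted p = 0.058). The call of Gne was lost whichever of the 6 E14 arrays was left out. Lists with under 5 tested genes were not tested as groups. Of the germline genes, Dazl, Taf7l and Ddx4 were at least 1.91-fold, 2.03-fold and 1.80-fold higher in EB2, with limma adjusted p from 0.000143 to 0.00119. Of the fibroblast markers, Mmp2 rose by 2.05 ± 0.12 and Fbn1 differed by 0.13 ± 0.27. Of the neuroectoderm genes, Sox21 fell by 2.81 ± 0.30.

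The effect of streptozotocin during embryoid body formation, the question the series title names, was measured by comparing treated with untreated EB2. Treated embryoid bodies had higher levels of naive pluripotency transcripts and lower levels of primed epiblast ones. They also had higher levels of p53 target and endoderm transcripts and lower levels of cholesterol synthesis transcripts. Camera called these 5 list shifts at the preset correlation and none of them with an estimated one (adjusted p from 0.29 to 0.36). The estimates were 0.511 for naive, 0.348 for primed, 0.38 for endoderm, 0.261 for cholesterol synthesis and 0.012 for p53 target genes. For p53 targets the estimate was near the preset 0.01, so correlation between genes does not account for the loss of that call. With an estimated correlation camera has only the 3 residual degrees of freedom. For general pluripotency genes, with an estimate of -0.018, the camera p before adjustment also rose, from 0.06 to 0.14. The adjusted p with an estimated correlation therefore do not measure correlation between genes alone. Limma's fry called all 5 of those list shifts (adjusted p from 0.0029 to 0.036). Klf4 rose from 8.14 ± 0.48 to 10.42 ± 0.30 on the log2 scale (SD, n = 2), or 4.85-fold, and Tbx3 rose 6.43-fold, while Fgf5 fell from 10.44 ± 0.36 to 9.14 ± 0.66, or 2.45-fold. Pou5f1 differed by -0.22 ± 0.08 (SE; limma adjusted p = 0.0926) and Sox2 by 0.46 ± 0.15 (limma adjusted p = 0.0525), and both passed with the replicate number as a block (adjusted p = 0.031 and 0.01). In all, 1560 of 8324 genes changed, 811 up and 749 down (1218 and 530 with median scaling, and 2492 genes with the replicate number as a block). At least 2-fold were 403, with groups not detected held at their bounds. The groups did not overlap in any of the 1560, against 58.8% of all genes and 33.3% by chance.

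Of the 13 naive genes 9 rose and 0 fell (12 rose adjusted over the list alone), with a median log2 change of 1.27 (camera adjusted p = 1.3e-06; adjusted p = 0.36 with an estimated correlation). That median was 1.9 without EB2 replicate 1 and 1.02 without EB2 replicate 2. Sox15 lost its call without treated replicate 2, with a log2 change of 0.87. Tbx3 rose by 2.68 ± 0.17, Nr5a2 by 1.56 ± 0.23 and Zfp42 by 1.46 ± 0.21, and Esrrb rose 2.83-fold. Nanog rose by 0.61 ± 0.14 (limma adjusted p = 0.0134), a call lost without EB2 replicate 2 (adjusted p = 0.06) or treated replicate 1 (adjusted p = 0.097). Of the 13 primed genes 11 fell and 0 rose by either count, with a median of -0.99 (camera adjusted p = 1.3e-06; adjusted p = 0.36 with an estimated correlation). Car14 fell by 1.86 ± 0.16 and Fgf15 by 1.34 ± 0.20. Pou3f1 and Sfrp2 lost their calls without treated replicate 1, with log2 changes of -1.05 and -0.87. Fgf5 fell by 1.29 ± 0.30 (limma adjusted p = 0.0136), but not past the test without EB2 replicate 2 (adjusted p = 0.096) or treated replicate 1 (adjusted p = 0.1). Of the 15 general pluripotency genes 4 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.11), with Tdh up by 1.69 ± 0.15, Dnmt3l by 0.81 ± 0.07 and also Sall4, whose call was lost without treated replicate 2 (adjusted p = 0.27). This list did pass without a filter on dim probes (camera adjusted p = 0.031) and with fry (adjusted p = 0.024), but its median was 0.11 without treated replicate 2 and 0.06 with the deposited log2 values.

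Of 15 primitive and visceral endoderm genes 10 rose and 0 fell (11 rose adjusted over the list alone). The median was 0.98, or 0.89 with the 5 members not detected in a group held at their bounds (camera adjusted p = 6.1e-06; adjusted p = 0.36 with an estimated correlation). Gata6, the transcription factor that specifies primitive endoderm, was not detected in EB2 and was at least 3.24-fold higher with streptozotocin (limma adjusted p = 0.000266). Foxq1 was at least 2.09-fold higher (limma adjusted p = 0.0016) and Lama1, the laminin chain of the endodermal basement membrane, rose by 1.66 ± 0.25. Without treated replicate 2 the calls of Col4a1, Col4a2, Lamc1 and Sox7 were lost, with log2 changes of 0.89, 0.65, 0.42 and 1.21. Of 20 p53 targets 10 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.56 (camera adjusted p = 6e-06; adjusted p = 0.29 with an estimated correlation). They included Plk2 (1.77 ± 0.15), Phlda3 (1.47 ± 0.15), the cell cycle inhibitor Cdkn1a (1.34 ± 0.17) and Mdm2, the ubiquitin ligase that limits p53 (1.21 ± 0.09). Aen lost its call without treated replicate 2, with a log2 change of 0.75. Of 15 cholesterol synthesis genes 9 fell and 0 rose (10 fell adjusted over the list alone). Their median was -0.57 (camera adjusted p = 6.1e-06, or 0.36 with an estimated correlation). Among those that fell were Dhcr7 (-0.88 ± 0.13), Cyp51 (-0.88 ± 0.13) and Fdps (-0.87 ± 0.10). Msmo1 and Mvd lost their calls without treated replicate 2, with log2 changes of -0.49 and -0.4.

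Of 11 LIF and Stat3 targets 4 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.013; adjusted p = 0.51 with an estimated correlation and 0.15 with fry). The members that rose were Klf4, Gbx2 (1.13 ± 0.13), Socs3 (1.26 ± 0.30) and Stat3 (0.84 ± 0.25). The list call was lost without EB2 replicate 2 (median 0.20, camera adjusted p = 0.096) or treated replicate 1 (median 0.29, camera adjusted p = 0.14), as were those of Socs3 (adjusted p = 0.093 and 0.11) and Stat3 (adjusted p = 0.21 and 0.29). Of 10 FGF and ERK response genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0045; adjusted p = 0.36 with an estimated correlation). Phlda1 rose by 1.66 ± 0.13 and the phosphatase Dusp4 by 1.09 ± 0.16, with Etv4 and Spred1, and Ier3 fell. The call of Spred1 was lost without treated replicate 1 (adjusted p = 0.27) and that of Ier3 without treated replicate 2 (adjusted p = 0.066).

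Other large rises were in Fgfbp1, an FGF carrier (at least 5-fold), Cabs1 (at least 5.13-fold), Fbp2 (at least 3.95-fold), Nt5e, the ecto-nucleotidase CD73 (8.50-fold), the drug efflux pump Abcb1b (8.44-fold), Lpar6 (7.25-fold), Mmrn2 (6.96-fold) and Emp1 (6.56-fold), with limma adjusted p from 4.03e-06 to 0.000227. Large falls were in Serpinf1 (at least 3.52-fold), the interferon-inducible GTPase Igtp (at least 3.53-fold), Vldlr, the VLDL receptor (at least 5.79-fold), Chac1, which breaks down glutathione (5.67-fold), Krt18 (5.36-fold), Rem2 (at least 2.88-fold), Pdlim3 (at least 3.52-fold), Pdlim4 (4.27-fold) and the MHC class I genes H2-T23 (at least 2.52-fold) and H2-Bl (4.31-fold), with limma adjusted p from 3.97e-05 to 0.00147.

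Camera found no shift for the other lists, with adjusted p from 0.083 to 0.81. Of 10 mesendoderm genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.63, or 0.34 with bounds), with Fgf8 at least 2.62-fold lower (limma adjusted p = 0.000296), Lefty1 down and Gata6, Nodal and Hhex up. The median was 0.39 without EB2 replicate 1, 0.29 without background correction, 0.27 with the deposited log2 values and 0.18 without a filter. Of 8 later mesoderm genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.44, or 0.20 with bounds), with Meis1 up by 2.28 ± 0.22, Bmp4 by 1.52 ± 0.26 and Pdgfra at least 1.16-fold, and Msx1 and Lmo2 down. Of 9 trophectoderm genes 1 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of -0.19 (0.15 without EB2 replicate 2), a mean of 0.02, Tfap2c up by 1.97 ± 0.28 and Krt18 and Krt8 down. Of 11 O-GlcNAc and hexosamine genes only Renbp passed (0.70 ± 0.15; median 0.26), and Ogt differed by 0.34 ± 0.16 (limma adjusted p = 0.17) and Nagk by 0.60 ± 0.19 (limma adjusted p = 0.0519). With the replicate number as a block both passed (adjusted p = 0.012 and 0.0058), while the list did not (camera adjusted p = 0.28). In the unfolded protein and integrated stress list 0 of 15 rose and 4 fell (0 and 5 adjusted over the list alone; median -0.13). These were Chac1, Psat1, an enzyme of serine synthesis (-1.43 ± 0.09), Trib3 (-1.38 ± 0.32) and Herpud1 (-0.85 ± 0.18). Glycolysis and hypoxia had 2 of 20 up and 5 down (median -0.08), with the angiogenic factor Vegfa down by 1.88 ± 0.26 and Egln3 by 1.49 ± 0.16, Aldoc, Pfkl and Tpi1 also down, and Ndrg1 and Slc2a3 up. Heat shock had 2 of 8 up, Hspb1 at 1.72 ± 0.10 and Dnajb1 (median 0.11). Limma's fry did call that list (adjusted p = 0.012, mean 0.3). Base excision repair had Xrcc1 of 16 up and Mutyh down (2 and 2 adjusted over the list alone; median -0.05), and the mitotic list 0 of 13 up and Plk1 down (0 and 0 adjusted over the list alone; median 0.00). Of these calls, those of Hhex, Lefty1, Lmo2, Msx1, Krt8, Xrcc1, Mutyh, Dnajb1, Plk1 and Herpud1 were lost without treated replicate 1 (adjusted p = 0.16, 0.098, 0.19, 0.055, 0.071, 0.26, 0.25, 0.14, 0.3 and 0.051). Those of Nodal, Ndrg1, Pfkl and Tpi1 were lost without treated replicate 2 (adjusted p = 0.098, 0.13, 0.21 and 0.055). Mgmt, which removes alkyl groups from guanine, differed by 0.77 ± 0.25 (limma adjusted p = 0.052; 0.021 with the block). Of the lists too short to test, Sox21 rose by 2.60 ± 0.30, the fibroblast markers Thy1 and Mmp2 fell by 1.76 ± 0.20 and 1.10 ± 0.12, and Dazl, Ddx4, Stk31 and Taf7l of the germline list did not pass, with differences from -0.24 to 0.71.

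**Figure D2:**
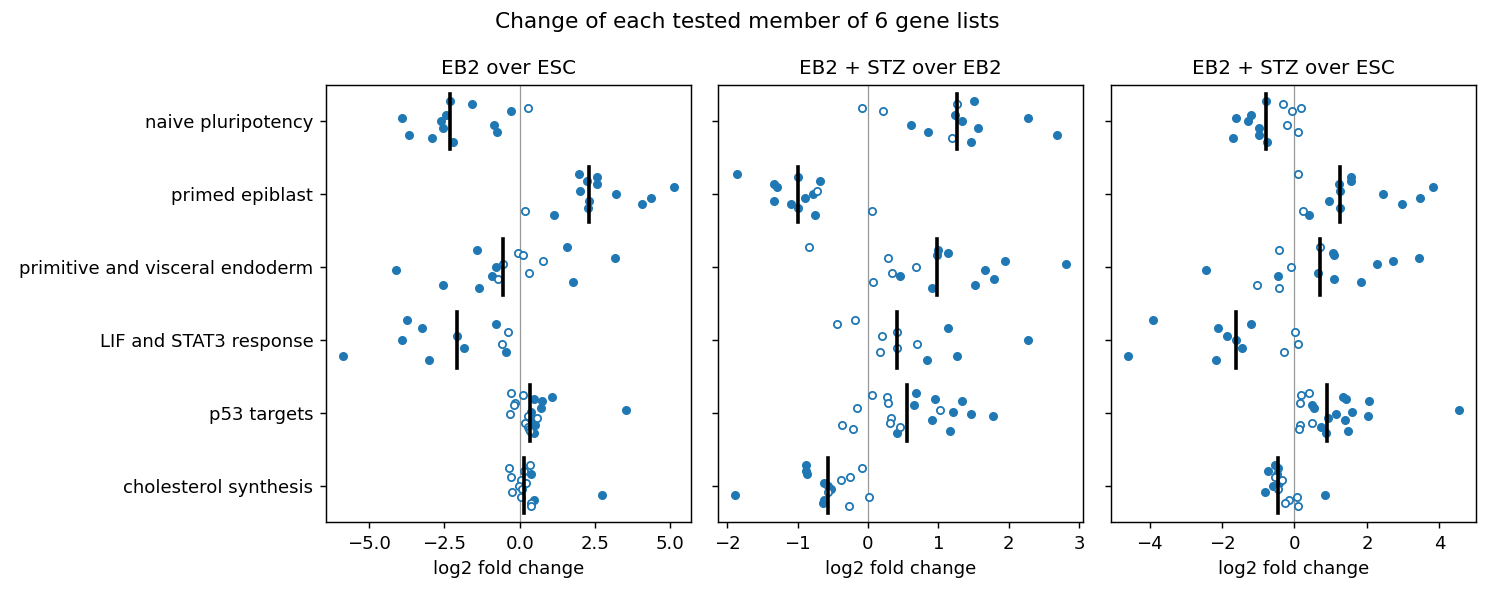
log2 fold change (horizontal axis) of each tested member of 6 gene lists in the 3 comparisons of E14 groups (filled points passed the test at an adjusted p under 0.05, open points did not; black bars are medians). Naive genes had a median of -2.30 in EB2 over ESC and of 1.27 with streptozotocin over EB2, primed genes of 2.30 and -0.99, and p53 targets of 0.35 and 0.56.

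Genes changed by streptozotocin were mostly genes that embryoid body formation had changed the other way. Of the 1560 genes, 1058 (67.8%) had changed in the opposite direction between ESC and EB2, 59 (3.8%) in the same direction, and 443 (28.4%) had not changed. Of genes that rose in EB2, 562 fell with streptozotocin against 146 for independent lists, and of genes that fell in EB2, 496 rose against 131. Simulated unchanged groups sharing the EB2 arrays gave at most 1 gene called in both comparisons, and 0 when the arrays also shared deviations by replicate number at the largest correlation seen (0.401). These groups held no change, so few calls could arise in either comparison. The simulations do not show how many of the 1058 genes unrelated real changes would give through the shared EB2 arrays. With the replicate number as a block 1681 genes changed oppositely. The changes correlated across genes at -0.656. Shared arrays alone gave -0.5 in simulations, but a covariance of -0.015 against -0.25 in the data, and with a different EB2 array in each comparison the correlation was -0.585 or -0.545. The count of genes changed by streptozotocin was 781 without treated replicate 1 and 896 without treated replicate 2, and that of oppositely changed genes 560 and 692.

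**Figure D3:**
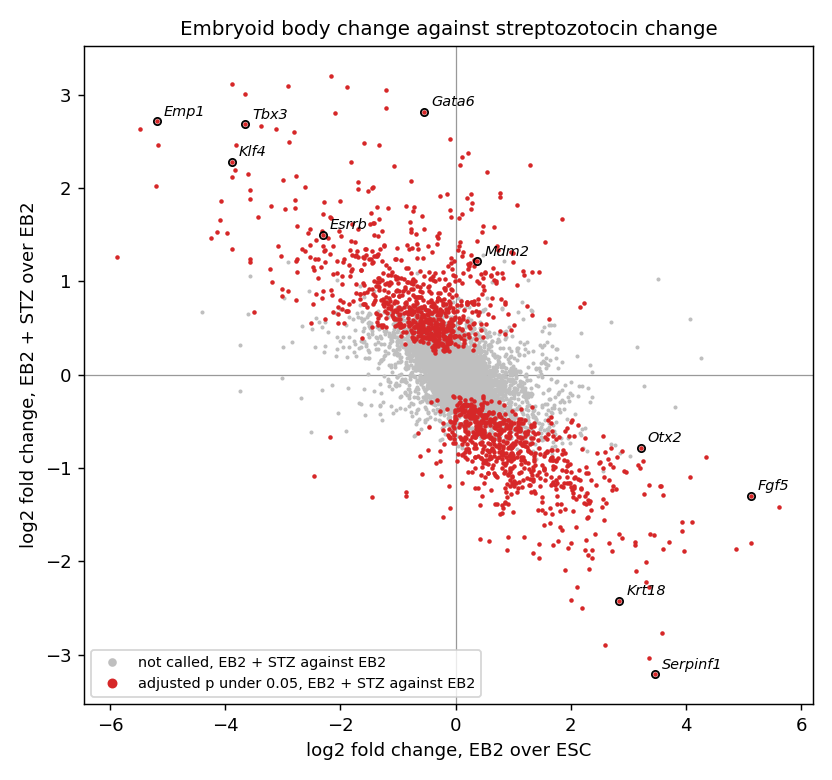
log2 fold change of EB2 over ESC (horizontal axis) against that of treated over untreated EB2 (vertical axis) for 8324 genes (red points passed the test for streptozotocin, grey points did not; 10 genes are named). The points run from upper left to lower right with a correlation across genes of -0.656, and Gata6 and Mdm2 lie high near the centre of the horizontal axis.

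Treated embryoid bodies were then compared with the starting ESC. They still differed from them in the direction of embryoid body formation for LIF targets, primed genes and naive genes, and p53 targets stood higher than in ESC. Camera called these list shifts at the preset correlation and none of them with an estimated one (adjusted p = 0.14 for p53 targets and 0.64 for the others). Socs3 was 24.5-fold lower than in ESC and Bcl3 at least 8.05-fold lower (limma adjusted p = 9.26e-06 and 2.28e-05). Fgf5 was at least 4.43-fold and Gadd45g 23.3-fold higher (limma adjusted p = 2.08e-05), and Cdkn1a rose by 2.07 ± 0.17 (SE, n = 2 per group). In all, 1849 of 8324 genes changed, 1119 up and 730 down (1075 and 1011 with median scaling, and 2852 genes with the replicate number as a block). At least 2-fold were 483, with groups not detected held at their bounds. Groups did not overlap in 63.8% of genes against 33.3% by chance. Of the 2968 genes changed in EB2, 1321 (44.5%) had changed the same way in treated embryoid bodies and 40 (1.3%) the opposite way. Of the 1321 genes, 804 rose in both against 218.2 for independent lists and 517 fell in both against 118. The changes correlated across genes at 0.766, with a covariance of 0.342, where simulated unchanged groups sharing the ESC arrays gave 0.501, a covariance of 0.015 and at most 2 genes called in both. Here too, groups without any change leave few calls that could overlap. The count of 1849 was 1199 without treated replicate 1, 1015 without treated replicate 2 and 1216 without ESC replicate 2.

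Of the 13 primed genes 11 rose and 0 fell (12 rose adjusted over the list alone; median 1.27, camera adjusted p = 1.6e-07; adjusted p = 0.64 with an estimated correlation), with Sall2 at 2.96 ± 0.21 and Otx2 at 2.43 ± 0.13. Of 11 LIF and Stat3 targets 8 fell and 0 rose (9 fell adjusted over the list alone; median -1.61, camera adjusted p = 2.2e-06; adjusted p = 0.64 with an estimated correlation). Of the 13 naive genes 8 fell and 0 rose by either count (median -0.80, camera adjusted p = 0.0023; adjusted p = 0.64 with an estimated correlation and 0.13 with fry), with Klf4 at -1.61 ± 0.22, Klf5 at -1.28 ± 0.17 and Klf2 at -1.21 ± 0.12. Nanog differed from ESC by -0.22 ± 0.14 (limma adjusted p = 0.288). Pou5f1 fell by 0.28 ± 0.08 (limma adjusted p = 0.034), a call lost without ESC replicate 1 (adjusted p = 0.24), treated replicate 1 (adjusted p = 0.12) or treated replicate 2 (adjusted p = 0.15). Those of Esrrb (-0.80 ± 0.21, limma adjusted p = 0.021) and Zfp42 (-0.76 ± 0.21, limma adjusted p = 0.0289) were likewise lost without ESC replicate 1 (adjusted p = 0.082 and 0.091), ESC replicate 2 (adjusted p = 0.086 and 0.12) or treated replicate 2 (adjusted p = 0.11 and 0.12), and that of Zfp42 without treated replicate 1 (adjusted p = 0.056).

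Of 20 p53 targets 14 rose and 0 fell (15 rose adjusted over the list alone; median 0.90, camera adjusted p = 4.2e-09; adjusted p = 0.14 with an estimated correlation), including Plk2 (2.04 ± 0.15) and Mdm2 (1.59 ± 0.09). Of 15 cholesterol synthesis genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.45, camera adjusted p = 0.0055; adjusted p = 0.64 with an estimated correlation and 0.13 with fry), with Dhcr7 at -0.72 ± 0.13. That list call was lost without ESC replicate 1 (camera adjusted p = 0.06). Other large rises were in Grm6 (at least 10.4-fold), Enpp2 (at least 9.57-fold), the cyclin Ccno (at least 8.62-fold), Slc40a1 (21.9-fold), Dab2, an endocytic adaptor of visceral endoderm (10.9-fold), Nrcam (at least 3.96-fold) and Tnfrsf19 (at least 3.81-fold), with limma adjusted p from 4.04e-06 to 0.000392. Other large falls were in Pmel (at least 7.14-fold), Myl4 (13.2-fold), Krt17 (10.8-fold), Msc (9.09-fold), Serpinb6c (7.74-fold), the amino acid transporter Slc38a5 (at least 4.42-fold), Ceacam20 (at least 3.02-fold) and Igsf21 (at least 2.90-fold), with limma adjusted p from 6.19e-06 to 0.000284.

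Camera found no shift in the remaining lists, with adjusted p from 0.058 to 0.86. Endoderm genes went both ways, with 8 of 15 up and 2 down (8 and 5 adjusted over the list alone; median 0.71, or 0.23 with bounds and -0.42 among genes detected on all 6 arrays). Foxq1 was at least 1.99-fold and Gata6 at least 3.09-fold higher (limma adjusted p = 0.000153 and 0.000501), and Lama1 fell by 2.44 ± 0.25, with Lamc1. Of 10 FGF and ERK genes 1 rose and 6 fell (2 and 6 adjusted over the list alone; median -0.47), with Spry4 down by 1.66 ± 0.15 and Dusp4 up by 1.60 ± 0.16. Of 15 general pluripotency genes Dppa4 and Zscan10 rose and Pou5f1, Dnmt3l and Tdh fell (median -0.09). Of 10 mesendoderm genes Eomes, Gata6, Lefty1 and Nodal rose and Chrd, Lefty2 and Sp5 fell (4 and 4 adjusted over the list alone; median 0.16, or -0.03 with bounds). Of 8 later mesoderm genes Msx1, Pdgfra and Twist1 rose and Bmp4 fell (4 and 1 adjusted over the list alone; median 0.57, or 0.39 with bounds). Of 9 trophectoderm genes Cdh3 and Eomes rose and Krt8, Peg10 and Tead4 fell (2 and 4 adjusted over the list alone; median -0.27). Of 11 O-GlcNAc and hexosamine genes Gne rose and Gfpt2 fell by 1.04 ± 0.14 (median 0.06, mean -0.04). Of 16 base excision repair genes Lig3 and Xrcc1 rose and Apex1 fell (median 0.03), and of 15 genes of the unfolded protein and integrated stress response Psat1 fell (median -0.17). Of 20 genes of glycolysis and hypoxia Ddit4 rose and Ndrg1 fell by 1.18 ± 0.20, with Aldoc, Pfkp, Slc2a1 and Vegfa (1 and 6 adjusted over the list alone; median -0.03). The mitotic list had 0 of 13 up or down (median 0.09), and in heat shock Bag3 and Dnajb1 rose and Hspb1 fell (8 tested; median 0.02, with camera's direction down).

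Many of these small changes were lost when 1 array was left out. The calls of Bag3, Lig3 and Msx1 were lost whichever treated or ESC array was left out, so they lay near the threshold. Each gene is listed here under 1 such array, although several were lost without others too. Without treated replicate 2 the calls of Dppa4, Zscan10, Eomes, Lefty2, Msx1, Peg10, Lig3, Bag3 and Slc2a1 were lost (adjusted p = 0.13, 0.26, 0.09, 0.28, 0.23, 0.12, 0.11, 0.18 and 0.12). Without treated replicate 1 those of Pdgfra, Gne and Xrcc1 were (adjusted p = 0.1, 0.12 and 0.11). Without ESC replicate 1 those of Tdh, Sp5, Apex1 and Dnajb1 were (adjusted p = 0.21, 0.067, 0.24 and 0.21), and without ESC replicate 2 those of Twist1, Tead4, Krt8, Vegfa and Lamc1 (adjusted p = 0.25, 0.17, 0.19, 0.15 and 0.094). Thy1 fell by 1.34 ± 0.20 and Mmp2 rose by 0.95 ± 0.12. Taf7l, Ddx4, Dazl and Stk31 were at least 3-fold, 2.17-fold, 1.61-fold and 1.37-fold higher than in ESC, with limma adjusted p from 0.000138 to 0.00135.

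Streptozotocin was also added to ZHBTc4 cells kept in doxycycline, so its effect can be described in cells without detectable Pou5f1. With 1 array each, the differences have no replicate check and were not tested. The series holds no array of ZHBTc4 without doxycycline, and these were stem cells and not embryoid bodies. A contrast with E14 therefore does not show what the loss of Pou5f1 does. All 20 p53 targets were higher with streptozotocin, with a median log2 difference of 0.82 (percentile 100 among random lists). Plk2 was 4.30-fold, Bbc3 3.91-fold, Phlda3 3.71-fold and Trp53inp1 3.37-fold higher. All 17 trophectoderm genes measured were higher (median 0.61, percentile 100), including Gata2 (2.66-fold), Dlx3 (2.51-fold) and Krt7 (2.12-fold), and Wnt7b was at least 4.04-fold higher. Cholesterol synthesis genes were lower, 13 of 15 with a median of -0.50 (percentile 0), including Mvd (-0.89), Lss (-0.81) and Dhcr7 (-0.75). Of 8549 genes, 87 were at least 2-fold higher and 18 at least 2-fold lower, with genes not detected on 1 array held at their bounds. Among genes detected on both arrays of a pair, 89 differed at least 2-fold here and 9, 19 and 16 between replicate arrays of the 3 E14 groups. Without background correction, which stretches dim differences, 40 did here (37 with the deposited log2 values) and 5, 8 and 2 between replicates. The SD of the differences was 0.339, against 0.246 to 0.294 between replicates.

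Naive genes were higher by a median of 0.25 (9 of 11, percentile 99.9), with Klf4 at 0.46, Klf5 at 0.34 and Nanog at 0.33, although the member with the largest difference, Gdf3, was lower (-0.48). Esrrb (-0.09) and Zfp42 (0.20) differed by less than the replicate SDs. The percentile takes no account of genes that move together, as naive genes did between replicates in E14 (estimated correlation 0.511). It therefore does not set the median of 0.25 against the spread between replicates. Primed genes lay at a median of -0.41 (9 of 11 lower, percentile 0), with Slc7a3, a transporter of cationic amino acids, at -1.13 and Otx2 at -0.77. Mesendoderm genes lay at 0.37 (percentile 99.7), with Nodal at 1.30 and Sp5 at 0.84, endoderm genes at 0.20 (percentile 98.9; -0.05 among genes detected on both arrays and -0.02 without a filter), and mitotic genes at 0.17 (percentile 99.4). The unfolded protein and integrated stress list lay at -0.23 (percentile 0) and FGF and ERK genes at -0.20 (percentile 1.5), although Fos (1.32) and Egr1 (0.70) were higher. The medians and percentiles of the others were -0.05 and 27.4 for general pluripotency, -0.15 and 18.9 for later mesoderm, -0.01 and 53.9 for LIF and Stat3, and 0.01 and 58.5 for the O-GlcNAc and hexosamine list. They were -0.05 and 29.9 for base excision repair, -0.11 and 2.5 for glycolysis and hypoxia, and 0.07 and 91.6 for heat shock. Sox2 was lower, at -0.76, and Ogt differed by -0.13. The largest single differences upward were in Svop (4.78-fold), Dcxr (4.38-fold), Gata6 (4.32-fold), Plk2, Bbc3, the epoxide hydrolase Ephx1 (3.75-fold), Dnaic1 (3.73-fold) and Phlda3. Those downward were in Serpinf1 (3.30-fold), Chac1 (2.71-fold), Id4 (2.52-fold), Phgdh, which starts serine synthesis (2.38-fold), Ccnd2 (2.38-fold), Gpt2 (2.23-fold), Slc7a3 (2.20-fold) and Slc1a4 (2.12-fold).

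The effects of streptozotocin in the lines, which share no array, correlated across 7878 genes at 0.391. Of the 1420 genes changed in EB2 and measured in ZHBTc4, 1059 (74.6%) differed in the same direction there, with medians of 0.20 for the 755 that rose in EB2 and -0.17 for the 665 that fell. At least 2-fold in both, with bounds, were 30 genes upward and 8 downward, among them Gata6, Plk2, Phlda3, Svop and Ephx1 upward and Serpinf1, Chac1, Phgdh, Gpt2 and Slc1a4 downward. By the same count the only gene at least 2-fold in opposite directions was Oasl2, which was chosen after its values were seen. Without bounds there were 4, among them Id4, which was 2.52-fold lower with streptozotocin in ZHBTc4 and rose in E14 from a level not detected in EB2 (limma adjusted p = 0.00323). The embryoid body changes correlated at -0.123 with the effect in ZHBTc4.

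**Figure D4:**
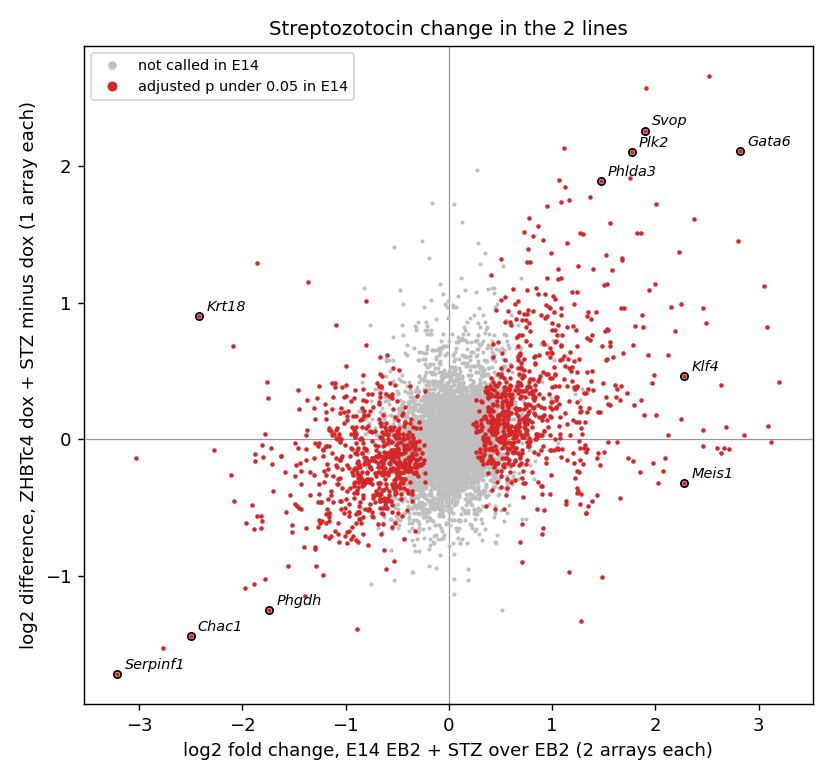
log2 fold change of treated over untreated EB2 in E14 (horizontal axis, 2 arrays each) against the log2 difference of ZHBTc4 with doxycycline and streptozotocin minus doxycycline alone (vertical axis, 1 array each). Red points passed the test in E14 and grey points did not, the correlation across 7878 genes is 0.391, and Krt18 and Meis1 lie on opposite sides of zero in the lines.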

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

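The effect of streptozotocin was compared between E14 embryoid bodies (2 arrays per group) and ZHBTc4 cells with doxycycline (1 array each). Genes named for treated against untreated EB2, and fixed lists, are listed when both treated E14 arrays lay on 1 side of both untreated ones, past the limma test. In ZHBTc4 they also had to differ the other way or not at all. Genes named on other grounds are not listed, among them Oasl2 and Spred1 (0.36 in E14 and -0.49 in ZHBTc4). Id4, also not listed, rose in E14 from a level not detected in EB2 and differed by -1.33 in ZHBTc4. The difference between the lines was not tested for any of them. Of 72 named genes that passed in E14, 61 were measured on both ZHBTc4 arrays and 16 went the other way there or were level to 2 decimals. For scale, the SD of log2 differences between replicate E14 arrays was 0.269, so the smaller differences below are within that spread.

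Krt18 fell by 2.42 ± 0.18 in E14 and differed by 0.90 in ZHBTc4, where its log2 intensity went from 8.88 to 9.79, and its partner keratin Krt8 fell by 0.80 ± 0.16 and differed by 0.28. The LIM-domain gene Pdlim4 fell by 2.09 ± 0.18 and differed by 0.68. Thy1 fell by 1.76 ± 0.20 and differed by 0.42, and the matrix protease Mmp2 fell by 1.10 ± 0.12 and differed by 0.41. The mitotic kinase Plk1 fell by 0.35 ± 0.11 and differed by 0.01. The E14 calls of Krt8 and Plk1 were lost without treated replicate 1 (adjusted p = 0.071 and 0.3).

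Gbx2 rose by 1.13 ± 0.13 and differed by -0.47. Lama1 rose by 1.66 ± 0.25 and differed by -0.43. Meis1 rose by 2.28 ± 0.22 and differed by -0.32. Socs3 rose by 1.26 ± 0.30 and differed by -0.24, and Stat3 rose by 0.84 ± 0.25 and differed by 0.00; both E14 calls were lost without treated replicate 1 (adjusted p = 0.11 and 0.29). Dusp4 rose by 1.09 ± 0.16 and differed by -0.13. Esrrb rose 2.83-fold and differed by -0.09, Emp1 rose by 2.71 ± 0.28 and differed by -0.07, and Sox21 rose by 2.60 ± 0.30 and differed by -0.06. The FGF and ERK response list had a median of 0.42 in E14 (limma camera adjusted p = 0.0045; adjusted p = 0.36 with an estimated correlation) and of -0.20 in ZHBTc4.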

How the results depend on the processing

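The only result past the threshold that reversed was Irgm1 in treated EB2 against ESC, whose probes disagree: -0.26 with the brightest probe and 0.55 (adjusted p = 0.014) with the mean of all. Besides the results given here, 12088 values of named genes, changed list members and lists were recomputed: 11276 stayed on their side of the threshold or, in ZHBTc4, within the SD between replicates (86 of them, none past the threshold, changed sign), 575 lost the threshold, 126 gained it and 110 ZHBTc4 values moved by more than the SD between replicates. The separate EB2 arrays, the bounded 2-fold counts, the replicate pairs set beside ZHBTc4 and the simulation with shared replicate deviations were chosen after seeing the data; every other alternative was fixed before. With a 2-fold minimum on the fitted change the counts were 1054 genes for EB2 against ESC, 492 for treated against untreated EB2 and 646 for treated EB2 against ESC, by construction; with groups not detected held at their bounds they were 837, 403 and 483. With an estimated correlation 0 of the 17 list calls held, and the naive (1.27) and primed (-0.99) medians had a camera adjusted p = 0.36. The calls lost included that of p53 targets, whose estimated correlation of 0.012 was near the preset 0.01, so the losses do not all come from correlation between genes. With an estimated correlation camera tests on the 3 residual degrees of freedom, which lowers its power. Fry, whose null is that a list's own genes do not move, called 18. Among them were heat shock genes with streptozotocin (fry adjusted p = 0.012), which camera did not call in the main fit. In EB2 against ESC fry, but not camera, called heat shock and general pluripotency genes (fry adjusted p = 0.006 for both). General pluripotency genes passed with streptozotocin without a filter (median 0.14, camera adjusted p = 0.031) and with fry (0.18, adjusted p = 0.024). Median scaling shifted the median of all genes by -0.142 for EB2 against ESC and by 0.101 for treated against untreated EB2. The share of changed genes that rose was then 35.0% in place of 54.7% and 69.7% in place of 52.0%, so the balance of rises and falls depends on the normalisation. Replicate numbers 1 and 2 are shared by the groups; deviations from the group means correlated at 0.265 (ESC and EB2), 0.253 (ESC and treated EB2) and 0.401 (EB2 and treated EB2), and nothing in the labels says that a number marks a shared culture or day. With the replicate number as a block, 2492 genes changed with streptozotocin, 2852 differed between treated EB2 and ESC, and 1681 changed oppositely; the count for EB2 against ESC stayed within 1.5 times. Leaving out each E14 array in turn, with the lone array of a group assumed to vary like the others, gave 2138 to 2679 genes for EB2 against ESC, 781 to 1442 for treated against untreated EB2, 1015 to 2023 for treated EB2 against ESC and 560 to 878 oppositely changed genes. The correlation of the embryoid body and streptozotocin effects ran from -0.691 to -0.600 over these fits and was -0.585 and -0.545 with separate EB2 arrays. That of the streptozotocin effects in the lines ran from 0.369 to 0.391, and was 0.401 without background correction and 0.362 without a filter. The 145 ZHBTc4 differences of at least 2-fold, without bounds, became 169 with cyclic loess, 175 with median scaling and 151 without a filter. They became 40 without background correction, 95 with an offset of 50, 89 among genes detected on both arrays and 37 with the deposited log2 values. Signal over background limits these, since background correction stretches differences of dim probes. A chip block was not run because the sources used here give no chip, and normalising the E14 arrays alone gives no ZHBTc4 value.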

Other observations

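The lists of ATF4 response, interferon and Oct4 target genes were chosen after the data were seen. So were the tests of separate EB2 arrays, of the straight line from ESC to EB2 and of stress genes in general, while those of normalisation, of single arrays and of the Oct4 slope were written before their results were seen. Many genes of amino acid synthesis and the response to the transcription factor ATF4 were lower with streptozotocin in both lines. The list was written after such genes had been seen among the falls, so its counts describe these arrays and no p-value is given. In E14, 18 of 26 fell and 0 rose, over all genes and over the list alone, with a median log2 change of -0.86. The serine synthesis enzymes Phgdh (-1.74) and Psat1 (-1.43), the mitochondrial folate enzyme Mthfd2 (-1.78), the transporter Slc1a4 (-1.97) and Chac1 (-2.50) were among them. In ZHBTc4, 23 of 27 were lower, with a median of -0.51, and 7 were at least 2-fold lower. In EB2 against ESC 13 of 26 had risen and 0 had fallen (14 and 0 adjusted over the list alone; median 0.46), and in treated embryoid bodies 8 of 26 were below ESC and 0 above (8 and 1 over the list alone; median -0.24).

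Interferon and MHC class I genes, a list written in the same way and given no p-value either, split into groups that moved apart. With streptozotocin 13 of 23 fell and 5 rose by either count (median -0.66, or -0.31 with the 7 members not detected in a group held at their bounds). Those that fell included Igtp (at least 3.53-fold), H2-T23 (at least 2.52-fold) and H2-Bl (4.31-fold). Those that rose included Samd9l (1.99), Ddx58 (1.35), Eif2ak2 (0.65) and Trim25 (at least 1.16-fold). Each of these genes had moved the other way in EB2 against ESC: Igtp, H2-T23 and H2-Bl rose at least 3.19-fold, 2.28-fold and 5.68-fold, Samd9l, Ddx58 and Eif2ak2 changed by -1.69, -2.67 and -0.77, and Trim25 fell at least 1.47-fold. The list as a whole had 10 up and 9 down there by either count, with a median of -0.04 and a mean of 0.38. In ZHBTc4 the list had a median of 0.14, with Igtp at -0.14 and Oasl2 at 1.29. Without treated replicate 1 the call of Trim25 with streptozotocin was lost (adjusted p = 0.085), and without treated replicate 2 that of Eif2ak2 (adjusted p = 0.099). Mthfd2, Oasl2 and the named genes that rose were chosen after their values were seen.

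Of the 1560 genes that changed with streptozotocin, 1058 had changed the other way in embryoid body formation. Noise of single EB2 arrays would leave no correlation when each effect uses its own EB2 array. The correlation was -0.545 (95% interval across genes -0.569 to -0.518) and -0.585, which argues against noise of single arrays as the whole cause. A deviation common to both EB2 arrays would remain. It cannot be weighed, because the labels do not say whether replicates came from separate cultures. Quantile normalisation is argued against by a covariance of -0.245 under median scaling beside -0.25. A position on the straight line from ESC to EB2, 57.7% of the way, as the whole response would put few genes past both ends, but 329 genes changed in 1 direction against both EB2 and ESC (235 up and 94 down), where the threshold allows 78 false calls and simulations gave 0 to 11. A slower or partly blocked differentiation together with a separate response to the drug is a hypothesis that was not tested here, and treated and untreated embryoid bodies sampled at several times would test it. Transient genes, which peak or dip on the way, stay open as part of the 329.

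The rise of p53 targets with streptozotocin was seen in both lines. A rise of stress genes in general would take in the unfolded protein and integrated stress list. Its median was -0.13 in E14 (95% interval of the difference from p53 targets 0.35 to 1.35) and -0.23 in ZHBTc4 (0.66 to 1.57), which argues against a rise of that list. For heat shock genes the E14 interval, -0.02 to 0.92, includes zero. Limma's fry called heat shock genes with streptozotocin in E14 (adjusted p = 0.012, mean log2 change 0.3). A rise of heat shock genes is therefore not argued against there. The unfolded protein and integrated stress list holds Chac1 and Psat1, also among the ATF4 response genes that fell, so its median may reflect that fall. These intervals resample genes, which are not independent replicates. The array of a single replicate is argued against by the fits without 1 array, in which the camera adjusted p was at most 1.9e-05, but with an estimated correlation it was 0.29. DNA damage by an alkylating agent could give this pattern. That is a hypothesis, since damage was not measured and any action of streptozotocin on O-GlcNAcase was not separated from it. Markers of DNA damage in treated cells, beside an alkylating agent that spares O-GlcNAcase, would test it.

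Known Oct4 targets marked in the deposited table, 319 of 403 of them tested, also moved back. In EB2 against ESC 56 rose and 122 fell (61 and 131 adjusted over the list alone), and with streptozotocin 92 rose and 26 fell (112 and 34; median 0.18). The slope of their streptozotocin change on their embryoid body change was -0.402, inside the range for random gene sets of the same size matched on the embryoid body change (-0.475 to -0.368, median -0.421), so they may have moved back no more than other genes with such changes did. In ZHBTc4, without detectable Pou5f1, their median difference was -0.01 (percentile 80). This does not show a dependence on Pou5f1, since the series holds no array of ZHBTc4 without doxycycline.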
